A study of Mus musculus with 8 samples.

How the data were processed

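RNA-seq of total RNA was measured in 8 libraries of the mouse 4T1 cell line, 2 each of parental, Tyro3-overexpressing parental, anti-PD1 resistant and Tyro3-knockout resistant cells, grouped by the phenotype and genotype in the labels. The cells were grown in DMEM with serum and had no treatment, per the labels' protocols. The authors deposited 3 tables, each for 1 comparison of 4 libraries. Per the file headers, the authors gave raw read counts per gene, and these are whole numbers that are equal for a library in both tables that hold it. The deposited normalized values are a signal, in that each is the count divided by 1 size factor per library set within its table. The authors also deposited FPKM values, per the file headers, a log2 fold change per gene, and a p-value and adjusted p-value per gene. CASAVA, STAR and DESeq2 are named, without version or role, in the submitters' processing notes, with the builds GRCm38 and mm10. The counting program and its use of strand are not given in the sources used here. The log2 fold changes, FPKM, p-values and normalized values of the authors were not used in the tests.

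The counts of the 3 tables were joined by gene identifier into 24677 genes, of which 20265 stood in every table. A gene not listed in a table was set to 0 in its libraries, since unlisted genes had at most 1 read there. In the tables, 24 symbols that had been turned into dates were restored by identifier. Start and end were equal to GENCODE release 21 of the mouse annotation (GRCm38) for 97.3% of the 99.96% of identifiers found in it. List members under older symbols were matched through the NCBI gene table of GRCm38.p6.

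Differences between groups were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on the deposited counts, with TMM scaling and filterByExpr, all 8 libraries and 1 mean per group in 1 fit. The design was fixed before the data were examined, with 27 gene lists, the rule for named genes and the alternatives. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists of a comparison; the list of lymphocyte markers had 0 tested members. A contrast of knockout with parental cells and of resistant with overexpressing cells was added after seeing the data.

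Genes were named by the following rule. They were Tyro3 in each library, and Axl, Mertk, Gas6, Pros1, Slc3a2, Slc7a11, Gpx4 and Cd274 in each comparison. Per comparison, they were the 8 genes with the largest rise and the 8 with the largest fall among called genes with at least 5 CPM in the higher group, groups without overlap and a symbol that is not a predicted-gene name. Per list and comparison, they were up to 3 called members with the smallest adjusted p. They were also the 8 genes per direction with the largest smaller change among those opposite in overexpressing and knockout cells, and the 3 per direction with the smallest adjusted p for the difference between backgrounds. The text gives part of the genes so named, and some are not reported here. With 2 libraries against 2, chance leaves 33.3% of genes without overlap.

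Depth was 18001482 to 27261282 counted reads per library. A floor of 3 reads, 0.117 to 0.178 CPM, was used for a group with no read, and such floors cover counting error only. Replicates differed by more than counting noise in each group (chi-square over degrees of freedom 2.02 to 5.68), so none was counted as a duplicate. The common dispersion was 0.00123, a coefficient of variation of 3.51%.

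The test was tried on simulated counts with 200 changed genes and 1 further list of genes shifted by 0.5. Genes of low counts were not among the changed ones, so the shares called below do not cover them. For changes of 1 on the log2 scale it called 85.1% of them in overexpressing against parental (13436 genes), 83.6% in knockout against resistant (13817 genes) and 83.6% in resistant against parental (13424 genes). For changes of 0.5 it called 59.7%, 71.6% and 67.2% in the same order, and for changes of 2 it called 92.4%, 95.5% and 97.0%. Of all calls 4.92%, 6.12% and 9.23% were false. Of 9 unshifted lists, 0 were called in each comparison. Genes were simulated independently of each other and few were changed, so this does not show how often lists of correlated genes would be called.

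The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter, at least 50 reads in 2 libraries, fits of the 4 libraries of a comparison alone, an absolute log2 fold change of at least 1, the replicate number as a block, and each library left out in turn. For lists they were an estimated inter-gene correlation, fry, RLE scaling, the block and each library left out. An estimated correlation also leaves camera only the 4 residual degrees of freedom of the fit. Calls lost with it are thus not due to correlation alone. After seeing the data, 2 alternatives were added: leaving out ribosomal protein and mitochondrial genes, and removing each library's loess trend with GC content and gene length. Figures were drawn with matplotlib 3.10.9. Genes with near-identical copies, such as the Prl2c, Rps27, Ftl1 and class I MHC genes, have uncertain values where reads could be split between copies. Technical covariates were not fitted, since the labels give no batch.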

Results

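RNA-seq was done on 8 libraries of 4T1 cells, a mouse cell line of triple-negative breast cancer that grows in culture and as a transplanted tumour. The libraries fell into 4 groups of 2: parental cells, parental cells overexpressing Tyro3 (overexpressing, Tyro3_OE in the plots), cells resistant to anti-PD1 (resistant), and resistant cells in which Tyro3 was knocked out (knockout, Tyro3_KO in the plots). Anti-PD1 is an antibody against an inhibitory receptor of T cells. Tyro3 is a receptor tyrosine kinase of the TAM family, with Axl and Mertk, and Gas6 and Pros1 are its ligands. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The libraries held 18001482 to 27261282 counted reads, and 14513 genes passed the filter on low counts. Values are read counts scaled to a common library total (CPM) as mean ± SD with n = 2, changes are log2 fold changes with their standard error (SE), and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

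Tyro3 (ENSMUSG00000027298, chromosome 2, 119797733 to 119818104 in GRCm38, protein coding) was measured in each library first. It stood at 25.6 and 24.4 CPM in the parental libraries and at 107 and 102.9 CPM in the overexpressing ones. It stood at 20.7 and 21.2 CPM in the resistant libraries and at 3.81 and 3.99 CPM (98 and 79 reads) in the knockout ones. Both engineered groups thus moved in the direction of their labels, by 2.07 (SE 0.07, adjusted p = 5.00e-28) and -2.43 (SE 0.11, adjusted p = 1.33e-23) on the log2 scale. Between resistant and parental cells the change was -0.25 (SE 0.08, adjusted p = 0.00586), which did not pass the threshold with upper-quartile scaling (adjusted p = 0.301) or in the authors' deposited table (adjusted p = 0.119).

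The first principal component, with 61.0% of the variance of log2 CPM, set the parental and knockout libraries apart from the overexpressing and resistant ones. The second, with 17.8%, set the overexpressing libraries apart from the resistant ones. Across genes, knockout libraries correlated with parental libraries at r = 0.981 to 0.982 and with the resistant libraries, the background they were labelled as made from, at 0.932 to 0.936. Overexpressing libraries correlated with resistant libraries at 0.963 to 0.966 and with parental libraries at 0.957 to 0.959. Libraries of one group correlated at 0.990 to 0.994. The resistant libraries also had the highest share of reads in ribosomal protein genes (8.81% and 9.12%, against 5.09% to 6.07% in the other groups) and in mitochondrially encoded genes (2.98% and 3.23%, against 1.99% to 2.42%).

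**Figure D1:**
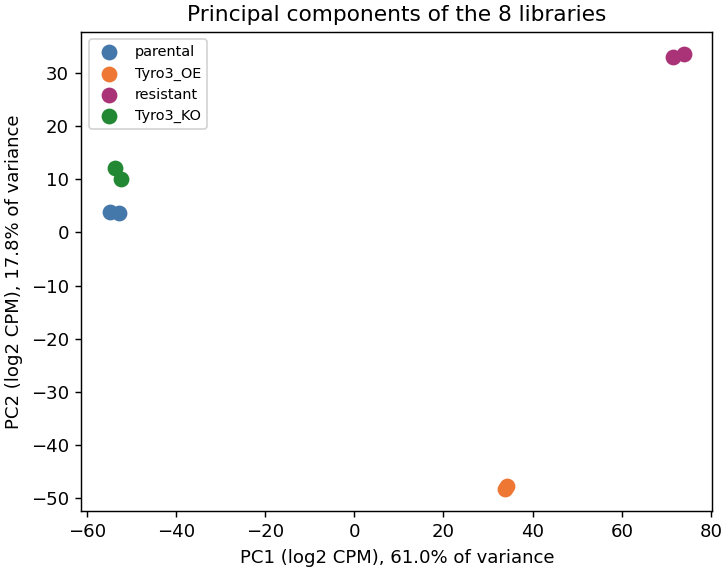
Principal components 1 and 2 of the log2 CPM of 14513 genes, each point 1 of the 8 libraries, coloured by group. Component 1 holds 61.0% of the variance and has the parental and knockout libraries at its negative end.

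The first comparison asked which genes differed when Tyro3 was overexpressed in parental cells. Genes of the type I interferon response, which viral nucleic acid and interferons induce, rose in the overexpressing cells: all 34 measured members were called higher, with a median log2 fold change of 2.80 (adjusted p = 2.27e-12 by camera, and 0.0477 with an estimated correlation). Oasl2 rose by 4.06 (SE 0.12), from 3.25 ± 0.10 to 54.1 ± 0.95 CPM, Parp14 by 3.26 (SE 0.10) and Ifi27 by 2.10 (SE 0.08). Cholesterol synthesis genes fell, with all 21 measured members called lower and a median of -1.49 (adjusted p = 2.05e-10, and 0.0477 with an estimated correlation).

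Genes of the cell cycle and of protein folding were lower in the overexpressing cells. All 29 mitosis genes were called lower (median -0.91, adjusted p = 6.56e-12, and 0.0727 with an estimated correlation), among them Ube2c at -1.52 (SE 0.04) and Ccnb1 at -1.44 (SE 0.04). Of 28 S phase genes 24 were lower and 1 higher (median -0.68, adjusted p = 1.88e-06, and 0.0546 with an estimated correlation), and Rrm2, a subunit of ribonucleotide reductase, changed by -1.47 (SE 0.04). All 12 heat shock genes were lower (median -1.05, adjusted p = 1.75e-06, and 0.0895 with an estimated correlation), with the chaperones Hsph1 at -2.18 (SE 0.04) and Hspa8 at -1.44 (SE 0.04). Of 16 glycolysis genes 13 were lower and 2 higher, and of 26 NRF2 target genes, which answer oxidative stress, 21 were lower and 4 higher (adjusted p = 0.000197 each, and 0.209 each with an estimated correlation). Nqo1, an NRF2 target, changed by -2.22 (SE 0.06), and Ldha, which makes lactate, by -1.38 (SE 0.04). Of 18 unfolded protein response genes 11 were lower and 4 higher (adjusted p = 0.0355, and 0.457 with an estimated correlation), with the chaperone gene Calr at -1.997 (SE 0.04).

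The genes of the ATF4 amino acid response rose, 24 of 26 being called higher and 2 lower (median 1.20, adjusted p = 6.81e-08, and 0.0895 with an estimated correlation). The median was 1.01 with a gene that had no read in the parental libraries at its lower bound. Trib3 went from 27.6 ± 0.32 to 517.8 ± 20.9 CPM (4.23, SE 0.05), Atf5 rose by 2.82 (SE 0.05), and Slc7a11 and Slc3a2, the subunits of the cystine importer, rose by 1.11 (SE 0.05) and 0.84 (SE 0.04). Gpx4, which reduces lipid peroxides, rose by 0.51 (SE 0.04). Of 19 genes of antigen processing and MHC class I 17 were higher and 2 lower (median 1.18, adjusted p = 1.95e-05, and 0.0546 with an estimated correlation), H2-D1 at 1.18 (SE 0.04), H2-T23 at 2.35 (SE 0.08) and the folding enzyme Pdia3 at -1.13 (SE 0.04). Cd274, which encodes PD-L1, rose by 2.38 (SE 0.22, adjusted p = 2.48e-13), from 1.90 ± 0.08 to 9.92 ± 1.17 CPM. Collagen and matrix genes were called as a list (12 of 20 higher and 3 lower, adjusted p = 0.00396, and 0.124 with an estimated correlation), with Col6a1 at 1.23 (SE 0.06). The median of that list went from 0.67 to 0.32 with GC content and gene length trends removed. So was the list of fibroblast markers (5 of 7 higher and 1 lower, adjusted p = 0.0355, and 0.199 with an estimated correlation), with Pdgfrb at 1.96 (SE 0.10). Rgs5, a pericyte marker, was at least 22.2-fold higher, against a floor of 3 reads per library in the parental cells, where it had none.

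Among single genes, Lbp and Hp, acute-phase proteins, rose from 0.98 ± 0.37 to 32.8 ± 0.09 CPM and from 0.96 ± 0.10 to 43.4 ± 2.48 CPM. Angptl6, a secreted angiopoietin-like protein, rose from 0.58 ± 0.02 to 22.7 ± 0.56 CPM. The ATP-gated channel gene P2rx3 stood at 0.026 ± 0.036 CPM (1 read) in parental and 7.07 ± 0.25 CPM in overexpressing cells, and Soat2, which esterifies cholesterol, at 0.13 ± 0.18 and 8.36 ± 0.14 CPM. S100a7a fell from 50.1 ± 1.10 to 3.72 ± 0.72 CPM and Wnt7a from 23.5 ± 1.41 to 1.24 ± 0.56 CPM. Prl2c3, of the prolactin family, fell from 42.4 ± 0.11 to 0.26 ± 0.14 CPM, a value that is uncertain because Prl2c2 is a near-identical copy.

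In all, 9613 genes were called at an adjusted p under 0.05, 4722 higher and 4891 lower in the overexpressing cells, of which 2713 changed by at least 1 on the log2 scale. With upper-quartile scaling, which moved the median of all genes to 0.17, 60.3% of the calls were higher, and 38.9% with GC content and gene length trends removed (median of all genes -0.10), against 49.1%. Of 26 lists tested, 12 were called by camera, and only those of interferon response and cholesterol synthesis also with an estimated correlation. The counts of members called were equal adjusted over the list alone for the 12 lists. Chemokine and cytokine genes (12 of 25 higher and 4 lower, adjusted p = 0.116) and NF-kB targets (10 of 17 higher and 4 lower, 11 higher adjusted over the list alone, adjusted p = 0.154) were not called as lists. The lists of TAM genes, ferroptosis defence, p53 targets, hypoxia response, macrophage markers and endothelial markers, none of them called, had a median and mean of different sign. Axl changed by -0.24 (SE 0.04). Pros1 had -0.13 (SE 0.08, adjusted p = 0.175), which passed the threshold with GC content and gene length trends removed (-0.20, adjusted p = 0.03165) and was 0.015 (adjusted p = 0.885) with upper-quartile scaling. Mertk, at 0.72 ± 0.07 and 0.66 ± 0.14 CPM, had -0.11 (SE 0.49, adjusted p = 0.853). Gas6 was not among the 14513 genes tested, so it has no value in any comparison.

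**Figure D2:**
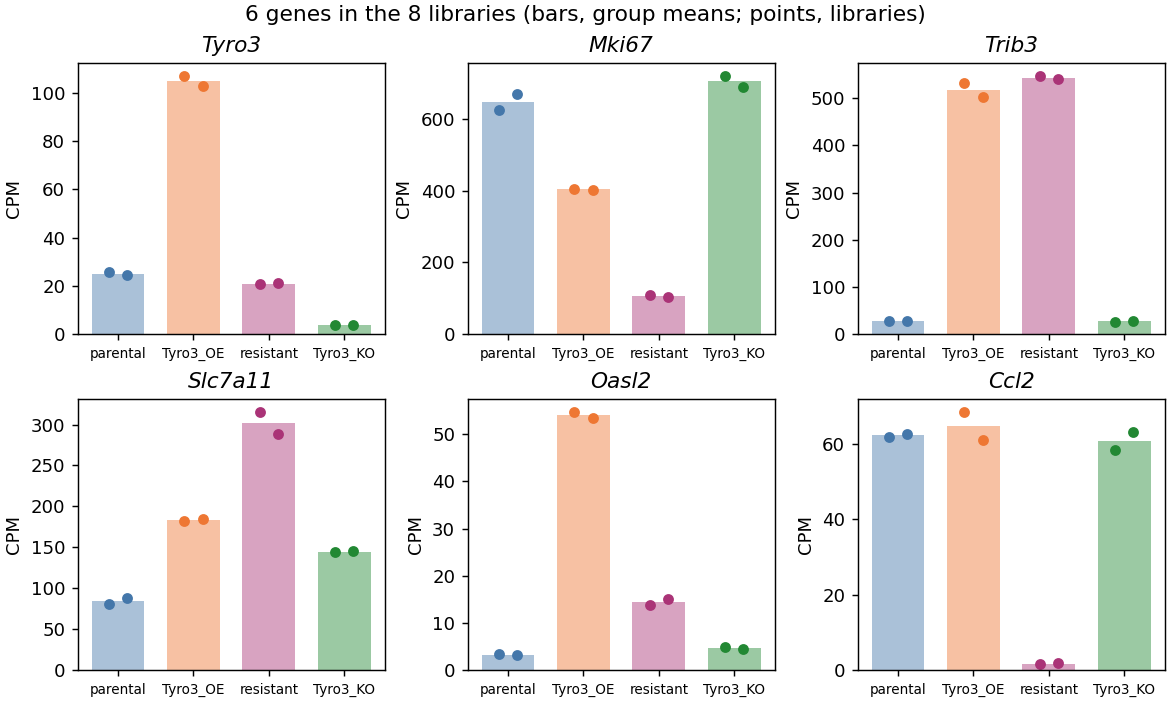
CPM of 6 genes in the 8 libraries, with bars for group means and points for libraries. Tyro3 follows the labels, Mki67 is lowest in the resistant cells, Trib3 is high in the overexpressing and resistant cells, Oasl2 is highest in the overexpressing cells at 54.1 CPM, and Ccl2 is at 1.70 CPM in the resistant cells and at 60.8 to 64.8 CPM in the other groups.

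The second comparison asked which genes differed when Tyro3 was knocked out in resistant cells. Cell cycle genes rose in the knockout cells: all 29 mitosis genes (median 2.36, adjusted p = 1.73e-14, and 0.0826 with an estimated correlation) and all 28 S phase genes (median 1.74, adjusted p = 8.57e-12, and 0.0544 with an estimated correlation) were called higher. The proliferation marker Mki67 went from 107.1 ± 3.05 to 703.8 ± 21.5 CPM (2.72, SE 0.04), Cenpf rose by 3.17 (SE 0.05), and Rrm2 by 3.52 (SE 0.05). All 21 cholesterol synthesis genes rose too (median 1.497, adjusted p = 1.41e-08, and 0.0692 with an estimated correlation). ATF4 response genes fell, 22 of 26 being lower and 3 higher (median -1.57, adjusted p = 3.52e-07, and 0.128 with an estimated correlation), with Trib3 at -4.29 (SE 0.05), Atf5 at -2.95 (SE 0.04), Slc3a2 at -1.40 (SE 0.04) and Slc7a11 at -1.06 (SE 0.04).

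Inflammatory genes were higher in the knockout cells. Of 17 NF-kB target genes 14 were higher and 1 lower (median 0.57, adjusted p = 0.000883, and 0.105 with an estimated correlation), and of 25 chemokine and cytokine genes 18 were higher and 5 lower (median 0.87, adjusted p = 0.0181, and 0.159 with an estimated correlation). Csf3, the granulocyte colony-stimulating factor, went from 8.96 ± 0.28 to 642.6 ± 11.6 CPM, Cxcl1, a neutrophil chemokine, from 11.96 ± 1.35 to 428.8 ± 0.67 CPM, and Lcn2, an iron-sequestering acute-phase protein, from 24.2 ± 0.93 to 509.4 ± 21.3 CPM. Vegfa, an angiogenic factor, changed by -2.90 (SE 0.04).

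Heat shock genes (11 of 12 higher and 1 lower, adjusted p = 0.000958, and 0.21 with an estimated correlation) and glycolysis genes (14 of 16 higher and 1 lower, adjusted p = 0.000472, and 0.222 with an estimated correlation) were higher. Interferon response genes (20 of 34 lower and 6 higher, adjusted p = 0.0255, and 0.222 with an estimated correlation) and MHC class I genes (14 of 19 lower and 4 higher, adjusted p = 0.0396, and 0.21 with an estimated correlation) were lower, H2-D1 at -1.24 (SE 0.04) and B2m at -1.04 (SE 0.04). The MHC class I list was not called without parental replicate 1 or without parental replicate 2 (adjusted p = 0.0509 each). The 13 mitochondrially encoded genes had 8 lower and none higher (adjusted p = 0.0281, and 0.361 with an estimated correlation), their median going from -0.32 to -0.079 with GC content and gene length trends removed, and the mitochondrial share of reads being 2.98% and 3.23% in resistant and 2.03% and 2.13% in knockout libraries. Their call was lost without resistant replicate 1 (adjusted p = 0.0733) and without knockout replicate 2 (adjusted p = 0.05015).

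Cdh17, a cadherin, went from 0.18 ± 0.002 to 31.5 ± 3.97 CPM and Serpinb2, a plasminogen activator inhibitor, from 0.25 ± 0.03 to 41.7 ± 0.76 CPM. Prl2c2, with no read in the resistant libraries, was at least 122-fold higher, and U90926 at least 88.1-fold higher, against a floor of 3 reads per library. Angptl6 went from 44.99 ± 3.81 to 0.79 ± 0.26 CPM, Lbp from 34.5 ± 1.74 to 1.32 ± 0.06 CPM, Bmf, a pro-apoptotic gene, from 26.5 ± 2.38 to 0.71 ± 0.07 CPM, and P2rx3 from 19.6 ± 2.76 to 0.050 ± 0.071 CPM (2 reads). Of the other TAM genes, Axl changed by 0.96 (SE 0.04), Pros1 by 1.80 (SE 0.08) and Mertk, at a low level, by -2.62 (SE 0.45). Gpx4 changed by -0.51 (SE 0.04) and Cd274 by -1.07 (SE 0.27, adjusted p = 0.000436).

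In all, 10552 genes were called, 5389 higher and 5163 lower in the knockout cells, and 3937 changed by at least 1 on the log2 scale. With upper-quartile scaling, which moved the median of all genes to -0.17, 41.8% of the calls were higher (4453 higher and 6206 lower), against 51.1%. Camera called 11 of the 26 lists, none of them with an estimated correlation, where fry, which asks whether members move on balance in 1 direction, called 23. The estimate itself was near or below the preset 0.01 for some of them, 0.0114 for S phase genes and -0.0147 for NF-kB targets. Correlation between members thus does not by itself account for these lost calls. The counts of members called in the 11 lists were equal adjusted over the list alone. The lists of NRF2 targets, immune checkpoint ligands, epithelial markers, collagens and matrix, fibroblast markers, endothelial markers and TAM genes, none of them called, had a median, mean and test that did not share 1 sign.

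The third comparison asked how resistant cells differed from parental cells. Cell cycle genes were lower in the resistant cells: all 29 mitosis genes (median -2.43, adjusted p = 1.23e-14, and 0.0713 with an estimated correlation) and all 28 S phase genes (median -1.80, adjusted p = 1.29e-12, and 0.0477 with an estimated correlation) were called lower, with Ccnb1 at -3.16 (SE 0.05), Tyms at -3.15 (SE 0.07) and Uhrf1 at -2.91 (SE 0.05). All 21 cholesterol synthesis genes were lower (median -1.78, adjusted p = 8.47e-10, and 0.0536 with an estimated correlation). ATF4 response genes were higher, 21 of 26, with 4 lower (median 1.36, adjusted p = 1.88e-05, and 0.193 with an estimated correlation). Slc7a11 (chromosome 3, 49892526 to 50443614) rose from 84.8 ± 5.30 to 302.3 ± 19.2 CPM (1.83, SE 0.05), Slc3a2 by 1.40 (SE 0.04) and Trib3 by 4.30 (SE 0.05).

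NF-kB targets were lower in the resistant cells, 15 of 17, with 2 higher (median -0.78, adjusted p = 0.000165, and 0.0713 with an estimated correlation), Tnfaip3 at -2.79 (SE 0.08) and Ier3 at -1.80 (SE 0.04). Of 25 chemokine and cytokine genes 16 were lower and 5 higher (adjusted p = 0.033, and 0.193 with an estimated correlation). The monocyte chemokine gene Ccl2 fell from 62.3 ± 0.61 to 1.70 ± 0.28 CPM and Csf3 by 4.31 on the log2 scale (SE 0.06), while Vegfa changed by 3.38 (SE 0.05). Heat shock genes (11 of 12 lower and 1 higher, adjusted p = 0.000913, and 0.202 with an estimated correlation) and glycolysis genes (13 of 16 lower and 1 higher, adjusted p = 0.00165, and 0.261 with an estimated correlation) were lower.

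Interferon response genes (21 of 34 higher and 4 lower, adjusted p = 0.0156, and 0.211 with an estimated correlation), collagen and matrix genes (12 of 20 higher and 2 lower, adjusted p = 0.01, and 0.193 with an estimated correlation) and mitochondrially encoded genes (9 of 13 higher and 3 lower, adjusted p = 0.033, and 0.313 with an estimated correlation) were higher. The median of the collagen list went from 0.85 to 0.51 with GC content and gene length trends removed. The call of the mitochondrial list was lost without resistant replicate 1 (adjusted p = 0.0694). The mitochondrial and ribosomal protein shares of reads given above were highest in the same libraries. Ftl1, a ferritin subunit with close copies in the genome and so an uncertain value, rose by 1.60 (SE 0.05), and Tfrc, the transferrin receptor, changed by -2.20 (SE 0.04). The lists of ferroptosis defence (8 of 20 higher and 7 lower, adjusted p = 0.377) and ferroptosis drivers (5 of 19 higher and 11 lower, adjusted p = 0.275) were not called.

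Cd74, the MHC class II invariant chain, stood at 0.085 ± 0.048 CPM (3 reads) in parental and 11.2 ± 0.85 CPM in resistant cells. Slc40a1, the iron exporter, stood at 0.051 ± 0.073 CPM (2 reads) and 6.37 ± 0.69 CPM, and Nos1 at 0.11 ± 0.09 and 9.33 ± 0.19 CPM. Id4, an inhibitor of helix-loop-helix factors, stood at 13.95 ± 1.76 and 0.13 ± 0.06 CPM, and Cdh17 at 22.9 ± 0.05 and 0.18 ± 0.002 CPM. Dsp, the desmosomal protein desmoplakin, changed by -3.86 (SE 0.12) and Vim by -2.18 (SE 0.04), whereas Fn1 changed by 1.99 (SE 0.04). Neither the epithelial (5 of 17 higher and 7 lower, adjusted p = 0.733) nor the mesenchymal list (3 of 16 higher and 10 lower, adjusted p = 0.108) was called. Axl changed by -1.05 (SE 0.04), Pros1 by -0.96 (SE 0.09), Mertk by 1.76 (SE 0.43) and Gpx4 by 0.18 (SE 0.04), the last lost with GC content and gene length trends removed (adjusted p = 0.259). Cd274 had 0.47 (SE 0.26, adjusted p = 0.101), which passed the threshold with upper-quartile scaling (adjusted p = 0.027) and without resistant replicate 2 (adjusted p = 0.034).

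In all, 10333 genes were called, 5092 higher and 5241 lower in the resistant cells, and 3980 changed by at least 1 on the log2 scale. With upper-quartile scaling, which moved the median of all genes to 0.19, 58.9% of the calls were higher (6264 higher and 4364 lower), against 49.3%. Camera called 11 of 26 lists, of which S phase genes also with an estimated correlation. Adjusted over the list alone the counts of members called were equal in these lists, except for 6 higher chemokine and cytokine genes in place of 5. MHC class I genes were not called as a list (13 of 19 higher and 5 lower, adjusted p = 0.0724), though they were without knockout replicate 1 (adjusted p = 0.049) or 2 (adjusted p = 0.0481). Not called either were NRF2 targets (13 of 26 higher and 11 lower, adjusted p = 0.377), whose median and mean differed in sign, as they did for checkpoint ligands and endothelial markers. For comparison, the authors' deposited tables had 7577 genes at an adjusted p under 0.05 for overexpressing, 8569 for knockout and 8368 for resistant cells. The settings differ: those tables listed 22670, 22621 and 22253 genes and held 4 libraries each. Here 14513 genes were tested in 1 fit of 8 libraries.

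**Figure D3:**
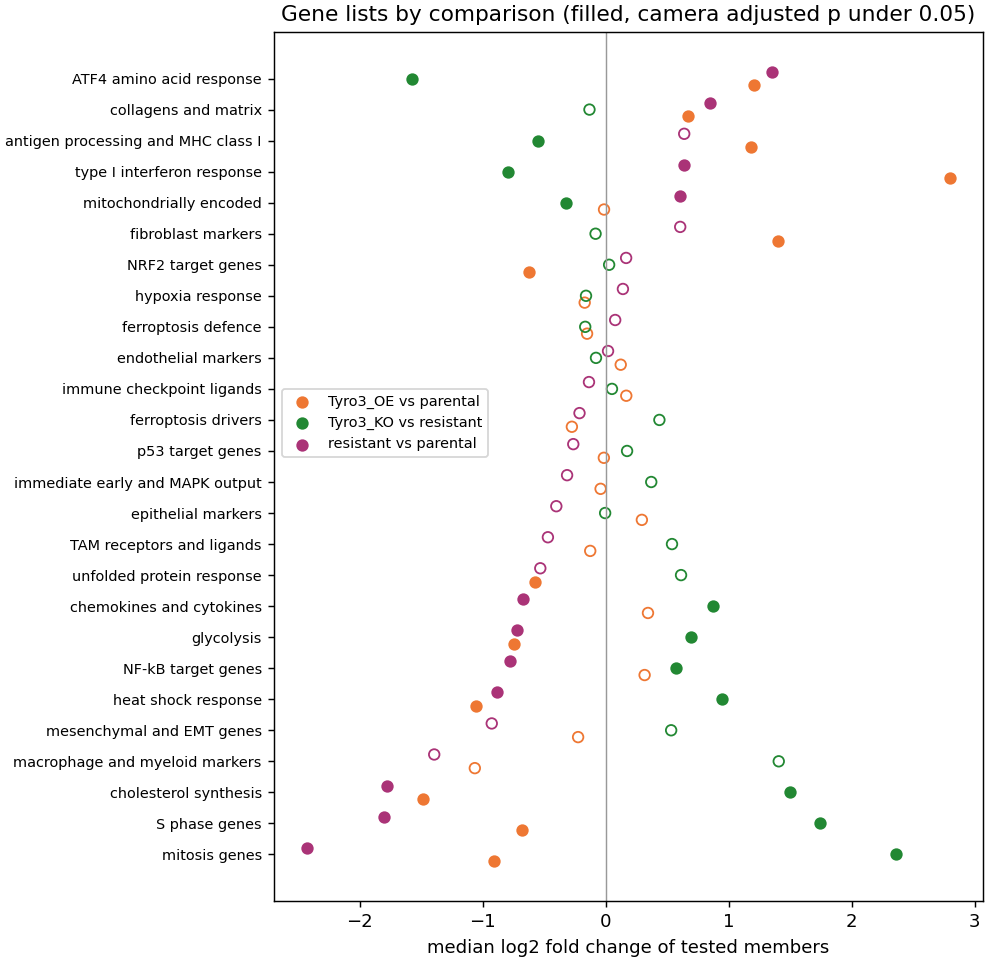
Median log2 fold change of the tested members of 26 gene lists in the 3 comparisons, filled where camera's adjusted p was under 0.05. Mitosis genes have medians of -0.91 in overexpressing against parental, -2.43 in resistant against parental and 2.36 in knockout against resistant cells.

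The design also asked whether genes followed Tyro3 in both directions. Genes that rose with overexpression and fell with the knockout included P2rx3, Soat2, Angptl6, Lbp, Pi16, Myo7a, Zfr2 and Trib3. Genes that fell and then rose included Prl2c3, Prl2c2, Wnt7a, Klk10, Shank2, S100a7a and Nipal1. Shank2 stood at 21.5 ± 0.64 CPM in parental, 2.01 ± 0.12 in overexpressing, 1.61 ± 0.17 in resistant and 18.4 ± 1.39 in knockout cells. Trib3 stood at 27.6 ± 0.32, 517.8 ± 20.9, 543.8 ± 4.63 and 28.0 ± 1.30 CPM in the same order.

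Of 7975 genes called in both comparisons, 7025 (88.1%) were called in opposite directions and 950 in the same direction. Of these, 3263 rose with overexpression and fell with the knockout, where 1680 were expected of independent lists, and 3762 did the reverse, where 1816 were expected (Fisher's exact test, odds ratio 0.0181). The 2 comparisons share no library. Across genes, which are not independent replicates, their log2 fold changes correlated at r = -0.58. Of the 7025 genes, 6631 (94.4%) were also called in resistant against parental cells in the direction of overexpression, where Tyro3 itself had -0.25. That comparison shares the parental libraries with the overexpression and the resistant libraries with the knockout comparison, so part of that share may come from the shared libraries. Independent lists would give 2503 such genes (35.6%). At most 1 arose in 20 simulations with parental and resistant cells at 1 common level and the other groups at their observed folds. That setting left at most 1 call in resistant against parental cells, so it cannot show how much of the 94.4% the shared libraries produce.

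**Figure D4:**
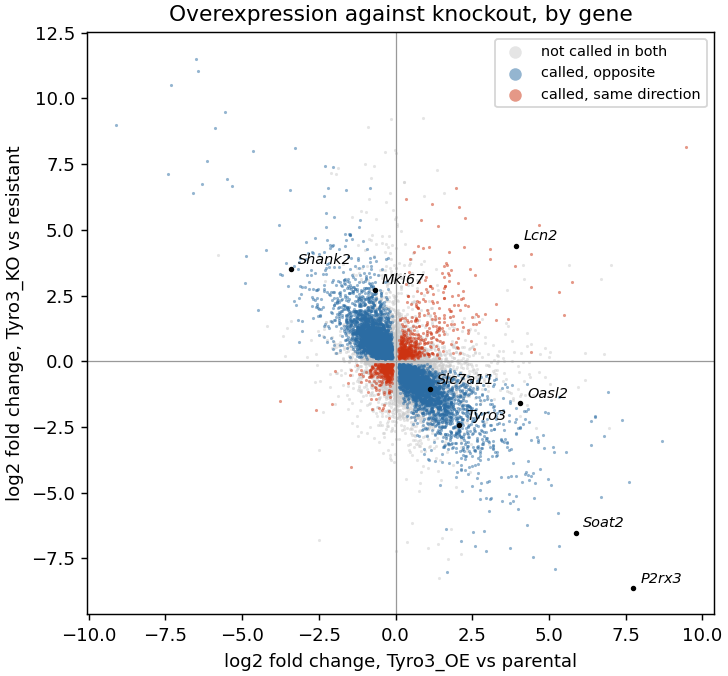
Fitted log2 fold change of each of 14513 genes with overexpression (x axis) and with the knockout (y axis), coloured by whether it was called in both and in which directions. The 7025 genes called in opposite directions lie in the upper left and lower right, with Lcn2 among the 950 called in the same direction; fitted values of genes with no read in a group are not bounded.

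Genes shared by overexpressing and resistant cells, both against parental cells, numbered 7558 (3563 higher, 3995 lower), where independent lists would give 1657 and 1766. They included Trib3, Angptl6, Lbp and H2-D1 among the higher genes and Calr and Hspa8 among the lower ones. Of the 10333 genes called in resistant cells, 8746 (84.6%) were called in the opposite direction in the knockout (reverted), among them Mki67, Ccl2 and Slc7a11. Of these 8746, 3318 (37.9%) were still called in knockout against parental cells, so part of them did not return to the parental level. The overexpression and resistant comparisons share the parental libraries, and the resistant and knockout comparisons share the resistant ones. Unchanged groups simulated against the same controls gave at most 1 shared or reverted gene in 20 simulations. Groups without change yield almost no calls, so that count cannot show how many of the genes come from the shared libraries. The simulated correlations were 0.565 and -0.469 against the observed 0.732 and -0.857, and the covariances 0.0786 and -0.0508 against the observed 0.956 and -1.398. The simulations used the spread between libraries of a group, so they miss a deviation common to both libraries of a control. The 2 control libraries were not split, since each part would hold 1. Part of the excess may thus still come from such a deviation of the shared controls.

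The last comparison asked whether the difference between cells with more and with less Tyro3 was the same in both backgrounds. The neutrophil-related genes Lcn2, Csf3 and Cxcl1 had the smallest adjusted p among those with a larger value in the parental background, with differences of 8.32 (SE 0.07), 6.51 (SE 0.07) and 6.54 (SE 0.08) on the log2 scale. Lcn2 (chromosome 2, 32384633 to 32388252) rose with overexpression, from 60.2 ± 0.28 to 913.7 ± 7.97 CPM, and also rose with the knockout. On the other side stood Thbs1, a matrix glycoprotein (-2.13, SE 0.06), Srxn1, a sulfiredoxin (-1.64, SE 0.06), and Rps27, a ribosomal protein gene with close copies and so an uncertain value (-2.09, SE 0.06). The rule that groups should not overlap cannot be applied to a difference of differences.

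Of 29 mitosis genes 29 and of 28 S phase genes 27 differed between backgrounds, with medians of 1.42 (adjusted p = 5.79e-18, and 0.0423 with an estimated correlation) and 1.06 (adjusted p = 3.49e-14, and 0.038 with an estimated correlation), the values being less negative for overexpressing against parental than for resistant against knockout cells. Interferon response genes had a median difference of 1.93 (29 of 34 higher and 1 lower, adjusted p = 5.11e-12, and 0.0423 with an estimated correlation) and NF-kB targets of 0.89 (13 of 17 higher and 1 lower, adjusted p = 3.60e-06, and 0.0423 with an estimated correlation). Cholesterol synthesis genes had a median difference of 0.06 and were not called as a list (7 of 21 higher and 6 lower, adjusted p = 0.773). In all, 6776 genes were called, 3588 with a higher and 3188 with a lower value in the parental background, and 38.2% were higher with GC content and gene length trends removed, against 52.95%, the median of all genes then being -0.12. Camera called 10 of 26 lists. Adjusted over the list alone, 31 interferon response and 15 chemokine and cytokine genes were higher, in place of 29 and 13, and the counts in the other lists called were equal. TAM genes, mesenchymal genes and p53 targets, none of them called, had a median and mean of different sign.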

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

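The tests of the difference between backgrounds and of the gene lists were planned before the data were examined; the GC content and length correction was added after the grouping of the libraries was seen but before its own result, and the tests of exchanged labels, culture conditions, immune cell RNA, vector and shared states were chosen after the results they bear on were seen.

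For 6776 genes, the difference between cells with more and with less Tyro3 was not equal in the 2 backgrounds, by edgeR's test. Tyro3 stood at 24.4 to 107 CPM in the parental and at 3.81 to 21.2 CPM in the resistant background. No vector-only or non-targeting library is among the samples, so an effect of Tyro3 cannot be told apart from other causes of this difference between backgrounds. The 10 lists called for that difference had these median differences: mitosis genes 1.42, S phase genes 1.06, interferon response 1.93, MHC class I 0.65, chemokines and cytokines 0.84, NF-kB targets 0.89, fibroblast markers 1.45, NRF2 targets -0.51, ATF4 response -0.30 (-0.47 with GC content and gene length trends removed) and mitochondrially encoded genes -0.39. With genes that had no read in a group at their bounds, the medians of fibroblast markers, interferon response and NRF2 targets were 1.34, 1.91 and -0.55. The lists of fibroblast markers, chemokines, MHC class I, NRF2 targets, ATF4 response and mitochondrially encoded genes were not called with an estimated correlation. Among single genes the differences were 8.32 for Lcn2, 6.51 for Csf3, 6.54 for Cxcl1, -2.13 for Thbs1, -2.09 for Rps27 and -1.64 for Srxn1.

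The knockout libraries lay close to the parental ones, differing from them at 5274 genes and from the resistant ones at 10552, whereas the overexpressing libraries lay only somewhat nearer to the resistant ones (8029 genes) than to the parental ones (9613 genes). Bias by GC content and gene length is argued against as the whole cause, since 88.3% of the genes called in opposite directions kept those calls when the trends were removed. Exchanged labels of the parental and resistant cells would bring this grouping about and stay open: neighbouring genes, which share copy number within a lineage, shared more excess variance along the labelled lineages (0.0109) than along the observed grouping (0.00451), but the difference of 0.00639 had a bootstrap interval of -5.99e-05 to 0.0148, and the split of engineered from other cells, which is neither, had 0.0063. Culture density or medium depletion that differed between library pairs cannot be told apart from the groups, since 0 of 6 protocol and source fields of the labels differ between samples, and an effect of Tyro3, the biological explanation the design names, also stays open.

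Interferon response genes were higher in overexpressing cells. RNA from immune cells is argued against, because Ptprc, which all leukocytes express, reached at most 0.132 CPM in those libraries. Of 14 leukocyte genes looked at, 0 reached 1 CPM, but that set left out Cd68, Cd14 and Cd74 of the macrophage list. Cd68 stood at 17.2 and 16.3 CPM in overexpressing and 8.14 and 8.78 CPM in parental libraries. Cd74 stood at 3.54 and 2.73 against 0.12 and 0.051 CPM, and Cd14, which was lower, at 25.7 and 24.1 against 55.5 and 48.8 CPM. The argument thus rests on Ptprc and the lymphocyte markers. The state shared with resistant cells is argued against as the whole cause, because all 34 genes were higher in overexpressing than in resistant cells, with a median of 1.79 (adjusted p = 6.64e-13 by camera, and 0.025 with an estimated correlation). A response to the expression vector or its delivery stays open, since 0 vector-only libraries are among the samples, as does an effect of Tyro3.

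NF-kB targets and chemokines fell in resistant cells and rose with the knockout, but were not called as lists with overexpression (adjusted p = 0.154 and 0.116). With an estimated correlation the lists were not called in resistant cells (adjusted p = 0.0713 and 0.193) or with the knockout (adjusted p = 0.105 and 0.159) either. A growth state shared to the same degree by overexpressing and resistant cells is argued against by the cell cycle genes. All 29 mitosis genes (median -1.51, adjusted p = 8.98e-19 by camera, and 0.039 with an estimated correlation) and all 28 S phase genes (median -1.08, adjusted p = 1.12e-16, and 0.025) were lower in resistant than in overexpressing cells. All 17 NF-kB targets were lower too (median -1.14, adjusted p = 5.59e-10, and 0.025 with an estimated correlation), but that largely restates the pattern to be explained. A state shared to a lesser degree by the overexpressing cells stays open, as does a difference between the backgrounds themselves, since the median of 0.32 with overexpression had a bootstrap interval over genes of -0.13 to 0.62 and was 0.081 with GC content and gene length trends removed.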

How the results depend on the processing

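Of 300 named-gene results, 291 kept their direction and side of the threshold under every alternative run for them. The required log2 fold change of at least 1 was not applied to named genes. Most of these genes were picked among called genes by size of change or adjusted p, so 291 does not show how stable calls are in general. The counts of genes called stayed within 1.5 times under the scalings, DESeq2, the filters, the 4-library fits and both added alternatives. With a log2 fold change of at least 1 required, which by construction lowers counts, they were 2713, 3937, 3980 and 1655 for overexpressing, knockout, resistant and the difference between backgrounds, 1577 opposite, 2958 reverted and 1898 shared genes. With an estimated correlation 2, 0, 1 and 4 lists were called in those comparisons, and with fry 23, 23, 24 and 23, against 12, 11, 11 and 10; fry does not compare a list with other genes. Leaving out 1 library gave 8642 to 9690, 9696 to 10751, 9644 to 10468 and 5999 to 6356 genes called, a lone library being assumed to vary like the others. It left 12, 10 to 11, 10 to 12 and 10 to 12 lists called. Calls were lost for MHC class I with the knockout without either parental library (adjusted p = 0.0509 each), and for mitochondrially encoded genes with the knockout without resistant replicate 1 (0.0733) or knockout replicate 2 (0.05015) and in resistant cells without resistant replicate 1 (0.0694). Calls were added for the unfolded protein response with the knockout without resistant replicate 1 (0.0403) and for MHC class I in resistant cells without knockout replicate 1 (0.049) or 2 (0.0481). In the difference between backgrounds they were added for epithelial markers without parental replicate 2 (0.0472), overexpressing replicate 1 (0.0478), resistant replicate 1 (0.0478) or knockout replicate 1 (0.0337), and for ferroptosis defence and collagens without resistant replicate 2 (0.048 each). The numbers do not pair the libraries (correlations of deviations -0.001 to 0.034), and the replicate block gave 9549, 10485, 10274, 6696, 6977, 8688 and 7498 genes. The block changed no call of a named gene, and of the list results it added epithelial markers in the difference between backgrounds (median 0.73, adjusted p = 0.0484, against 0.0515 without it).

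The direction of the test turned, with the median log2 fold change as given, in lists that camera did not call, and the cause was not tested. With fry these were, for overexpression, TAM genes (-0.13), p53 targets (-0.015) and hypoxia response (-0.17), and for the knockout TAM genes (0.54), epithelial markers (-0.0049) and fibroblast markers (-0.083). With RLE scaling it was hypoxia response (-0.17). Leaving out 1 library turned the hypoxia list (medians -0.23 to -0.11), p53 targets (-0.045 to 0.042), endothelial markers (-0.11 to 0.12), the mesenchymal list in the difference between backgrounds (-0.15 to -0.032) and Mertk with overexpression (-0.35 to 0.085). With upper-quartile scaling, which set the median of all genes to 0.17 with overexpression and 0.19 in resistant cells, Mertk (0.027) and Pros1 (0.015) with overexpression and Eng in resistant cells (0.014) turned sign. The 4-library fit could not be made for the difference between backgrounds, and the alternatives for normalized values were not run because the tables hold counts. Genes of a few reads, such as P2rx3 in parental cells, are limited by depth.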

Other observations

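The contrasts of knockout with parental and of resistant with overexpressing cells, the chromosome medians and the reading of the Tyro3 level as a hypothesis were chosen after the data were seen; the gene lists and the comparison of resistant with parental cells were planned.

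Against parental cells, camera called 5 of 26 lists in knockout cells, and none with an estimated correlation. Mitosis genes had a median of -0.06 (6 of 29 higher and 10 lower) and S phase genes of -0.10 (5 of 28 higher and 11 lower), and neither list was called by camera (adjusted p = 0.355 and 0.0787). Cholesterol synthesis genes were lower in knockout than in parental cells (15 of 21 lower, none higher, median -0.50, adjusted p = 4.15e-06, and 0.192 with an estimated correlation), as were ATF4 response genes (16 of 26 lower and 4 higher, median -0.21, adjusted p = 0.00308, and 0.452 with an estimated correlation). Collagen and matrix genes (11 of 20 higher and 2 lower, median 0.32) and fibroblast markers (4 of 7 higher, none lower, median 0.97) were higher in knockout cells, with an adjusted p of 0.00162 each, and 0.192 each with an estimated correlation. So were unfolded protein response genes (9 of 18 higher and 2 lower, median 0.15, adjusted p = 0.0474, and 0.651 with an estimated correlation). Adjusted over the list alone, 12 collagen and matrix and 10 unfolded protein response genes were higher, and the counts in the other 3 lists called were equal. Serpinb2 stood at 41.7 ± 0.76 CPM in knockout and 4.99 ± 0.59 CPM in parental cells, and Anxa8 at 25.9 ± 0.41 and 0.80 ± 0.03 CPM, while Krt7, a keratin, stood at 0.55 CPM in knockout and 24.8 CPM in parental cells. In resistant against overexpressing cells, camera called 11 of 26 lists, 4 of them also with an estimated correlation, and not all are given here. Among the 11, NRF2 targets were higher in resistant cells (21 of 26 higher and 1 lower, median 0.70, adjusted p = 2.20e-09, and 0.0809 with an estimated correlation). Median differences in log2 CPM from parental cells were taken by chromosome over genes with a mean of at least 5 CPM. In resistant, knockout and overexpressing cells in that order, they were -0.43, -0.31 and -0.11 for chromosome 13 and -0.38, -0.14 and -0.26 for chromosome 5. They were -0.21, -0.18 and -0.14 for chromosome 3, -0.19, -0.29 and -0.20 for chromosome 19, and -0.043, 0.29 and 0.11 for chromosome 1. These chromosomes were picked by no fixed rule, and the others are not given here.

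A hypothesis was that the Tyro3 mRNA level sets where a library lies. It is argued against as the whole cause, because Tyro3 was at -0.25 on the log2 scale in resistant against parental cells while these groups differed at 10333 genes. A part of the Tyro3 level in where the overexpressing and knockout libraries lie was not tested by this.

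The lists not described above gave no call with overexpression. They were immune checkpoint ligands (6 of 12 higher and 4 lower, adjusted p = 0.447), immediate early genes (8 of 25 higher and 12 lower, adjusted p = 0.158), hypoxia response (9 of 20 higher and 9 lower, adjusted p = 0.997), p53 targets (8 of 19 higher and 8 lower, adjusted p = 0.965), macrophage markers (2 of 5 higher and 3 lower, adjusted p = 0.737), endothelial markers (1 of 6 higher and 2 lower, adjusted p = 0.948) and TAM genes (1 of 5 higher and 2 lower, adjusted p = 0.763). The TAM list holds Tyro3 itself. Its median (-0.13) and mean (0.22) differ in sign.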
